A study of Sus scrofa with 16 samples.

How the data were processed

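RNA of liver, skeletal muscle (longissimus), uterine endothelium (the name given in the labels) and brain stem from 4 gilts, young female pigs of about 165 days, was compared on 16 arrays with 2 dyes. Each array carried 20400 oligonucleotides of 70 bases, per the labels' design text. Each gilt formed 1 loop of 4 arrays, in which every tissue was labelled once with Cy3 and once with Cy5, so that dye was balanced over tissues and the gilt was the replicate. Total RNA was extracted with TRIzol, amplified with a T7 oligo(dT) primer and coupled to the dyes, per the labels' protocols.

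The deposited table held 1 log ratio per row and array for 20736 rows, with no missing values. The scanner, background correction, normalization, log base and sign are not given in the sources used here. The authors' deposited values were read as log2 ratios because the largest absolute value, 10.42, would be 33586-fold as a natural log and 1372-fold as log2. This base is inferred. Array medians lay between -0.01 and 0.01 and array SDs between 0.52 and 1.00 on the log2 scale, so the arrays appeared already centred. No intensities were used here, so dim spots could not be separated from bright ones and depth in the sense of signal over background is unknown. The number of gilts limits the precision.

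The ratio was read as Cy5 over Cy3 on all arrays. Before the data were examined, a rule had been set that would turn every sign if most measured members of a list of muscle contractile genes came out lower in muscle. Only 1 member was measured, MYH7, with a muscle difference of -0.06 from the mean of the other tissues (limma adjusted p = 0.63). By its letter that rule would have turned the sign, and the main analysis departs from it. The departure was decided after the data were seen. It rests on 6 of 9 liver genes being highest in liver and MYOD1 being highest in muscle, with the ratio as Cy5 over Cy3. The liver genes and MYOD1 are thus not independent evidence of direction here. The direction is therefore likely, not settled, and counts with the sign turned are given with the other alternatives.

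The 4 ratios of each loop were solved by least squares into 4 tissue values per gilt, relative to the gilt's mean. The 16 values of each row were fitted with limma 3.58.1 in R 4.3.3, with gilt as a fixed block (9 residual degrees of freedom), default empirical Bayes moderation and Benjamini-Hochberg adjustment at a threshold of 0.05. The labels tie the values of a block to 1 animal, which is the basis of the pairing. Tests were an F test among the 4 tissues and 6 pairwise contrasts, all two-sided. A row was called highest in a tissue when it was above each of the other 3 past the threshold, and its size was the smallest of the 3 differences; calls of lowest mirrored this. A second count took differences of at least 1 on the log2 scale. All rows were tested, because the scrambled and mismatch control probes named in the design text were not separated from the rest here.

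On data simulated from the spread of the 20736 rows, with 200 rows changed in liver, the contrast of liver with brain stem recovered 53.0% of the 100 rows changed by 0.5 and 92.0% of the 100 changed by 1. Unchanged rows made up 4.61% of its calls. The contrast of skeletal muscle with uterine endothelium, in which no row was changed, gave 0 calls. The real contrast of liver with brain stem called 7796 rows, far more than were changed here, so these rates need not hold for the real data.

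A gene symbol was given for 178 rows, standing for 175 genes, and 0 rows had several symbols. All 178 were matched by gene identifier to the reference gene table, and 20558 rows stayed unnamed here. ASIP had 4 probes, which were averaged. No genome was used, so no positions are given. Genes were named by a rule set before the data were examined: per tissue the 10 with the largest size among those highest in it in every gilt and the 5 largest among those lowest in every gilt, and per pairwise comparison the 3 largest differences in each direction with 1 sign in all gilts. Other genes named as members of a list were chosen from that list.

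Of 22 gene lists set before the data were examined, 0 had the 5 named members needed for a test, and the largest number was 3. No reference gene was named. In their place 6 lists were drawn up from the names of the probes, after these were known and before any of their values was read: liver genes, neuronal and glial genes, skeletal muscle genes, genes of smooth muscle, stroma and epithelium, leukocyte genes, and genes of tissues not sampled. Each was tested in each tissue against the mean of the other 3 with limma's camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, with adjustment over the 24 tests. Alternatives set before the data were examined were median centring and scaling of arrays, fits of the 16 array ratios with a dye term and either no block or a random block by gilt, leaving out each gilt, robust moderation, a filter on missing values and a filter on rows of small SD. Others were chosen after the data were seen: 2 further centrings, leaving out the last 16 rows of each run of 432 rows, leaving out rows after a strong row (one with an absolute tissue value of at least 1), and turning all signs. Runs of 432 rows are a layout read from the values, not stated. Figures were drawn with matplotlib 3.10.9.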

Results

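The arrays compared 4 very different tissues of the same 4 gilts, liver, longissimus muscle, uterine endothelium and brain stem, in a study made to test a pig oligonucleotide array. Arrays of the same tissue pair with the same dyes correlated across rows with r between 0.66 and 0.95 over 5 pairs of arrays, and arrays with dyes swapped with r between -0.86 and -0.67 over 9 pairs. Rows are not independent replicates. All differences are on a log2 scale inferred from the values, and their sign, Cy5 over Cy3, is likely but not stated; a rule set in advance would by its letter have turned it on the strength of MYH7 alone, and with the sign turned every higher becomes lower. Tissue values are relative to the mean of the gilt's 4 tissues, and errors are SD over 4 gilts unless given as SE.

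Across the 4 tissues, 127 of the 175 named genes differed, and 12699 of all 20736 rows did so (61.2%, limma F test). CRP, the acute phase protein made by hepatocytes, stood at 2.47 ± 0.28 (SD, n = 4) in liver and at -0.89 ± 0.28 in muscle. MYOD1, a myogenic transcription factor, stood at 0.86 ± 0.12 in muscle and at -0.36 ± 0.05 in brain stem. MYH7, the slow myosin heavy chain, did not pass the test (limma adjusted p = 0.065), with -0.04 ± 0.09 in muscle; its row followed a strong row, here one with an absolute tissue value of at least 1. Among the genes of tissues not sampled, such as milk, sperm and retinal genes, 12 of 22 passed the F test. The median SE of a pairwise difference was 0.09.

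**Figure D1:**
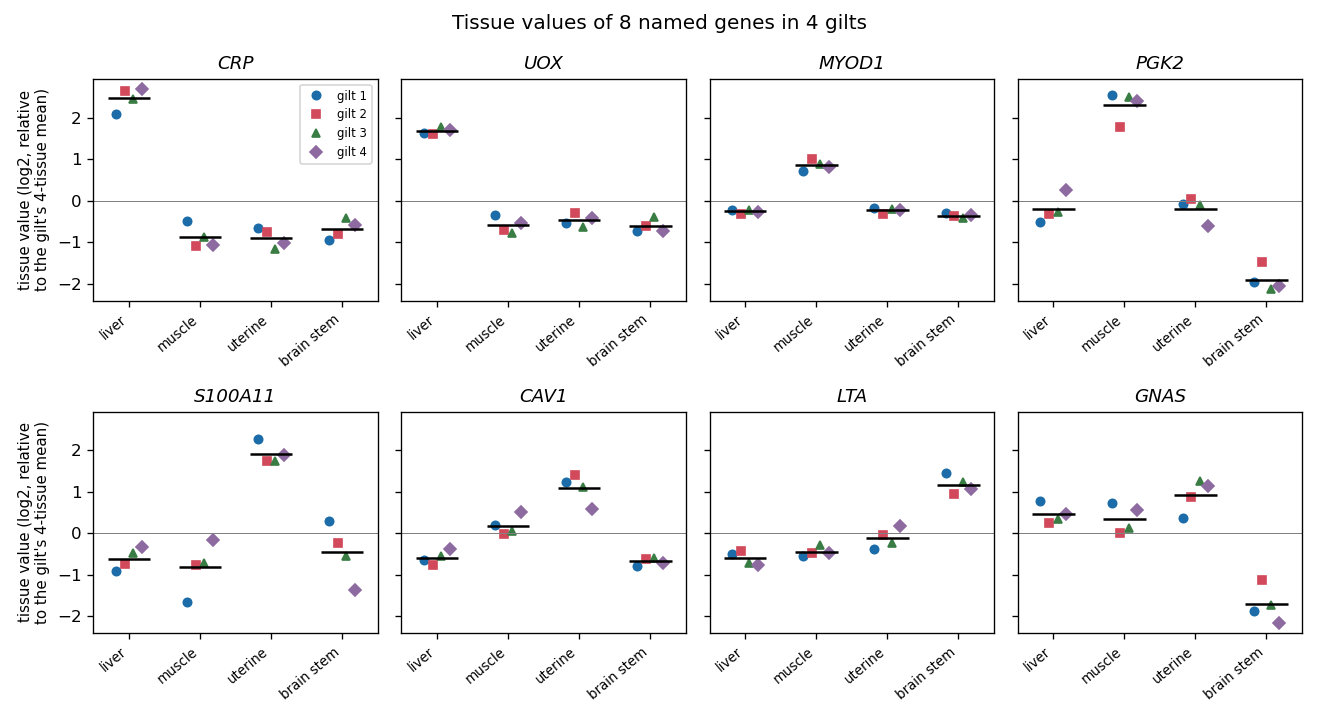
Tissue values (log2, relative to the mean of the gilt's 4 tissues) of 8 named genes; each symbol is 1 of 4 gilts and each bar the mean. CRP averaged 2.47 and UOX 1.68 in liver, PGK2 2.31 in skeletal muscle and S100A11 1.91 in uterine endothelium, while GNAS averaged -1.72 in brain stem.

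In liver, CRP exceeded the nearest other tissue by 3.16 ± 0.19 (SE; limma adjusted p at most 3.1e-07), and PROC, the anticoagulant protein C, by 2.70 ± 0.17. UOX, which oxidises uric acid, exceeded it by 2.15, the lectin MBL2 by 1.87, QDPR, which recycles tetrahydrobiopterin, by 1.11, and CYP7A1, the rate-limiting enzyme of bile acid synthesis, by 0.81. The ficolin FCN1 (1.63), the histamine receptor HRH4 (1.01), the sulfotransferase GAL3ST2 (0.88) and the cytokine IL1A (0.83) completed the 10 genes with the largest sizes. ITM2A was lowest in liver, at -0.51 from the nearest tissue. Of the 9 liver genes, 6 were highest in liver, while PGLYRP2 was highest in brain stem and CYP8B1 and VNN1 were highest in no tissue. Their median difference from the mean of the other tissues was 1.83, above 0 in 4 of 4 gilts (camera adjusted p = 6.9e-05; adjusted p = 0.20 with an estimated correlation). Adjusted over the list alone, 6 were higher and 1 lower. These genes also served to choose the sign and are not independent evidence of it. In all, 1473 rows were highest in liver and 92 lowest, of which 548 and 4 by at least 1. The number lowest was 37, 51, 20 and 60 without gilts 1, 2, 3 and 4, 160 with scaled arrays and 21 with tissues centred on the rows at the run ends, and the 4 ranged from 0 to 7. HRH4 lost its call without gilt 2 (0.86) or gilt 3 (0.97), and ITM2A without gilt 1 (-0.53), 2 (-0.55) or 3 (-0.42) or with the run-end centring (-0.47).

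Skeletal muscle was highest for PGK2, by 2.50 ± 0.23 (SE; limma adjusted p at most 2.6e-05). PGK2 is the testis form of phosphoglycerate kinase and its probe was not compared here with the close paralog PGK1, so the value is uncertain. KLF4, a transcription factor, exceeded the nearest tissue by 1.17 and MYOD1 by 1.09 ± 0.07. Smaller sizes were found for the neuropeptide gene ADCYAP1 (0.69), the antimicrobial peptide PR39 (0.64), SCAMP1 (0.52), KLK1 (0.47), the protamine PRM2 (0.44), the calcium channel subunit CACNB4 (0.37) and the oxytocin receptor OXTR (0.37). PDCD1LG2 was lowest in muscle (-0.23), and its row followed a strong row. Of the 3 skeletal muscle genes, MYOD1 and LMCD1 were highest in muscle and MYH7 was not. The row of LMCD1 also followed a strong row. The list had a median difference of 0.26, which did not pass with camera (camera adjusted p = 0.14) but did with fry (fry adjusted p = 4.5e-06). With rows that follow a strong row left out, MYOD1 alone remained of the list, at 1.14. MYOD1 also served to choose the sign, so neither it nor the list is independent evidence of it. Counts were 1475 rows highest and 140 lowest, of which 367 and 4 by at least 1. The number lowest was 82, 37, 55 and 90 without gilts 1, 2, 3 and 4, 280 with scaled arrays, 276 with no gilt block, 213 with a random block and 34 with the run-end centring, and the 4 ranged from 1 to 8. Calls were lost for KLK1 without gilt 2 (0.38) or 3 (0.43), for CACNB4 (0.24) and OXTR (0.31) without gilt 3, and for OXTR with tissues centred on the run ends (0.33). PDCD1LG2 lost its call without gilt 1 (-0.14), 2 (-0.23), 3 (-0.23) or 4 (-0.25) and with tissues centred on the most frequent value (-0.19) or on the run ends (-0.10).

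Uterine endothelium was highest for S100A11, a calcium-binding protein, by 2.37 ± 0.36 (SE; limma adjusted p at most 0.00042). CYBA, the light chain of cytochrome b558, exceeded the nearest tissue by 0.99 and CAV1, the main protein of caveolae, by 0.90. The immunoproteasome subunit PSMB8 (0.72), the proteasome activator PSME1 (0.66), FGF9 (0.40) and PAQR8 (0.28) were also highest there. The chemokine receptor CCR9 (-0.40), the acyl-CoA dehydrogenase ACADS (-0.39), the platelet integrin ITGA2B (-0.29) and IL12RB2 (-0.25) were lowest. The list of smooth muscle, stromal and epithelial genes had 3 higher, 3 lower and 6 that did not pass. Its median was -0.07 and its mean 0.37 (camera adjusted p = 0.79, fry adjusted p = 0.017). Leukocyte genes had a median of -0.08 with 2 higher and 4 lower of 22 (camera adjusted p = 0.38, fry adjusted p = 0.14). These 2 medians were -0.0336 and -0.0508 with tissues centred on the most frequent value and -0.0256 and -0.0429 on the run ends, and the latter was -0.0534 with no gilt block or a random one. The count of rows highest was 1187, with 128 lowest, of which 280 and 2 by at least 1. The count highest fell to 667 without gilt 2 and to 571 without gilt 3. The number lowest was 65, 53, 23 and 49 without gilts 1, 2, 3 and 4, 224 with no gilt block, 60 with tissues centred on the most frequent value and 16 on the run ends, and the 2 ranged from 0 to 2. PSME1 lost its call without gilt 1 (0.78), 2 (0.59) or 3 (0.65), PSMB8 without gilt 2 (0.57), PAQR8 without gilt 1 (0.24) or 4 (0.26), FGF9 without gilt 4 (0.38) or with the run-end centring (0.41). CCR9 lost it without gilt 2 (-0.30) or 4 (-0.37), IL12RB2 without gilt 1 (-0.25), 2 (-0.24) or 3 (-0.25), and ACADS without gilt 1 (-0.41), 2 (-0.31) or 3 (-0.43), with a random gilt block (-0.38) and with tissues centred on the most frequent value (-0.33) or on the run ends (-0.25).

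Brain stem was highest for LTA, the cytokine lymphotoxin alpha, by 1.29 ± 0.15 (SE; limma adjusted p at most 5.2e-05), and for the interferon gene IFNA1, by 1.03. Next came the sperm tail gene ODF1 (0.83), PGLYRP2 (0.77), the milk protein gene LALBA (0.71), the cartilage collagen COL10A1 (0.67), TLR10 (0.54), CRSP3 (0.52), IL17A (0.44) and the cone opsin OPN1SW (0.34). The row of LALBA directly followed that of CRP. GNAS, the stimulatory G protein alpha subunit, was lowest in brain stem by -2.07 ± 0.27 (SE), PGK2 by -1.70, PSME1 by -0.95, the folate receptor FOLR1 by -0.85 and IL1A by -0.73. Of 13 neuronal and glial genes, 3 were higher than the mean of the other tissues, 2 lower and 8 did not pass (median 0.06, camera adjusted p = 0.51); the median was 0.0350 without gilt 3, 0.0345 without gilt 4, 0.0278 with scaled arrays, 0.0107 with tissues centred on the most frequent value and -0.09 on the run ends. CEND1 was higher by 0.29 and GAD2, which makes GABA, by 0.34, while GLRB, a glycine receptor subunit whose row followed a strong row, was lower at -0.35. GAD2 differed by 0.19 without gilt 4, and with the run-end centring GAD2 (0.19) and CEND1 (0.14) lost their calls. Leukocyte genes had a median of 0.12 with 9 higher and 5 lower of 22 (camera adjusted p = 0.24, fry adjusted p = 0.010). Genes of tissues not sampled had a median of 0.06 and a mean of -0.0019, with 4 higher and 4 lower of 22 (camera adjusted p = 0.38, fry adjusted p = 0.17). With the run-end centring these medians were -0.02, with 5 leukocyte genes higher and 6 lower, and -0.08, with 2 genes of tissues not sampled higher and 5 lower; without gilt 3 the leukocyte median was 0.05, and without gilt 4 that of genes of tissues not sampled was 0.0407. Without rows of small SD these medians were 0.23 over 18 and 0.17 over 14 genes, and with tissues centred on the most frequent value 0.0742 and 0.0178. The count was 2012 rows highest and 1688 lowest, of which 372 and 517 by at least 1. Without gilt 3 there were 1259 highest and 1020 lowest, without gilt 4 996 lowest, and without gilt 2 1604 highest and 1709 lowest. With tissues centred on their most frequent value 1598 were highest and 2017 lowest, and with tissues centred on the run ends 977 and 2907. With that last centring IL17A (0.30) and OPN1SW (0.17) lost their calls, as OPN1SW did without gilt 3 (0.23) or 4 (0.32). FOLR1 lost its call without gilt 4 (-0.51) and with scaled arrays (-0.45).

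**Figure D2:**
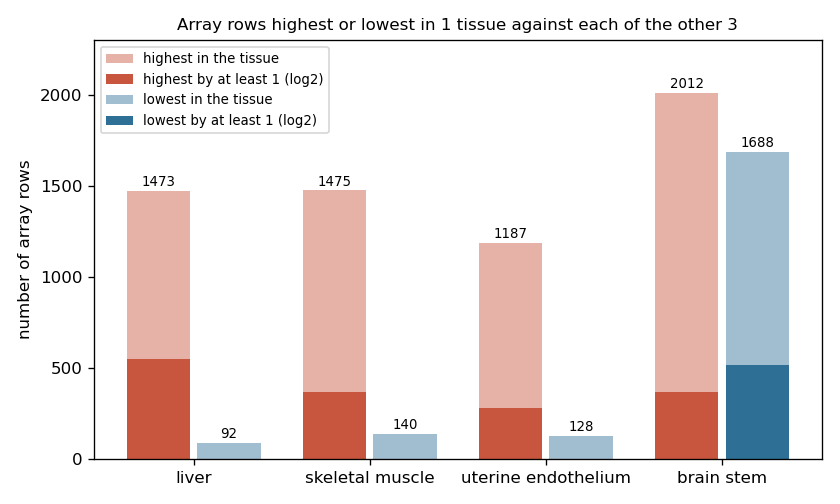
Number of array rows highest (red) or lowest (blue) in 1 tissue against each of the other 3, with the part that differed by at least 1 on the log2 scale in the darker shade. Liver, skeletal muscle and uterine endothelium had 1473, 1475 and 1187 rows highest and 92, 140 and 128 lowest, and brain stem had 2012 highest and 1688 lowest.

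Between liver and brain stem, the largest differences towards liver were those of CRP (3.16), PROC (2.75) and FOLR1 (2.67). ATP5G1, a subunit of mitochondrial ATP synthase, differed by -2.02, LTA by -1.78 and IFNA1 by -1.24. Of the named genes, 46 were higher and 35 lower in liver. Over all rows 7796 differed by limma, 4376 higher and 3420 lower in liver, of which 1484 and 688 by at least 1. The share higher was 56.1%, and 82.0% with tissues centred on the run ends (6946 higher and 1525 lower, with 15 named genes lower). Without gilt 3 there were 2140 rows and 17 named genes lower, and without gilt 1 or 4 there were 23 named genes lower.

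Liver exceeded skeletal muscle most for CRP (3.36), PROC (2.70) and TSPO, a protein of the outer mitochondrial membrane (2.42). PGK2 differed by -2.52, the transcription factor JUN by -2.07 ± 0.50 (SE) and KLF4 by -1.40. Of the named genes, 30 were higher and 26 lower in liver. Over all rows 5408 differed by limma, 2760 higher and 2648 lower in liver, of which 800 and 605 by at least 1. Without gilt 2 there were 1950 higher and 2027 lower, with tissues centred on the most frequent value 2698 and 2709, and without gilt 3 1682 lower. Named genes lower were 14 without gilt 2 or 3 and 15 with the run-end centring, and with a random block 32 were higher and 34 lower. JUN lost its call without gilt 1 (-1.96) or 2 (-1.95).

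Relative to uterine endothelium, liver was higher for CRP (3.37), PROC (2.82) and MBL2 (2.28). S100A11 (-2.53), JUN (-1.93) and CAV1 (-1.67) were lower in liver. Among the named genes 35 were higher and 13 lower in liver. Over all rows 4969 differed by limma, 2514 higher and 2455 lower, of which 639 and 512 by at least 1. The larger part of that near-even split turned under 5 alternatives, furthest with tissues centred on the most frequent value (2266 higher and 2700 lower). Without gilt 3 the count was 2785, with 1576 higher and 1209 lower and 20 and 6 of the named genes, and without gilt 2 there were 1539 rows and 6 named genes lower. JUN lost its call without gilt 2 (-2.02) or 3 (-1.74).

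Skeletal muscle exceeded brain stem most for PGK2 (4.22), GNAS (2.07) and JUN (1.87). LTA (-1.61), IFNA1 (-1.39) and the interferon gene IFN-DELTA-1 (-1.27) were lower in muscle. Of the named genes, 41 were higher and 31 lower in muscle. Over all rows 8103 differed by limma, 4434 higher and 3669 lower, of which 1329 and 607 by at least 1. The share higher was 54.7%, and 78.4% with tissues centred on the run ends, where 1605 rows and 12 named genes were lower.

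Relative to uterine endothelium, skeletal muscle was higher for PGK2 (2.50), KLF4 (1.17) and MYOD1 (1.09). S100A11 (-2.73), FOLR1 (-1.73) and TSPO (-1.63 ± 0.43, SE) were lower in muscle. Among the named genes 37 were higher and 18 lower in muscle. Over all rows 5475 differed by limma, 2760 higher and 2715 lower, of which 482 and 617 by at least 1. The larger part of the whole split turned under 7 alternatives, among them leaving out gilt 1 (2233 higher and 2254 lower) and a centring on the most frequent value (2543 and 2960). Without gilt 2 the count was 3436, with 1955 higher and 1481 lower, and the split at a size of 1 turned to 498 higher and 465 lower. Without gilt 3 the count was 3103, with 1655 higher and 1448 lower; named genes higher and lower were 18 and 11 without gilt 2 and 20 and 11 without gilt 3, and TSPO lost its call without gilt 2 (-1.83) or 3 (-1.74).

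Uterine endothelium exceeded brain stem most for GNAS (2.63), FOLR1 (2.57) and PSME1 (2.46). ATP5G1 (-1.83), LTA (-1.29) and IFNA1 (-1.03) were lower in uterine endothelium. Of the named genes, 29 were higher and 43 lower there. Over all rows 8662 differed by limma, 4703 higher and 3959 lower, of which 1568 and 479 by at least 1. The share higher was 54.3%, against 67.2% with tissues centred on the most frequent value and 80.7% on the run ends, where 1506 were lower. Without gilt 3 the count was 5611, with 2266 lower, and without gilt 4 2602 were lower. The split of named genes was 26 and 26 without gilt 3 and turned to 36 higher and 31 lower with the most frequent value as centre and to 37 and 19 with the run ends.

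A dye effect, the mean of the ratios around a loop, passed limma's test for 202 rows, of which 1 reached 1 on the log2 scale, and its median absolute size was 0.05. This test used the 16 array ratios with no gilt block, so arrays and not gilts were its replicates. Without 1 gilt the count ranged from 4 to 45.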

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

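The tests on genes of tissues not sampled, those on rows lowest in brain stem and the test on rows 18 and 24 away were chosen after the result was seen. In 7 of 84 values of named genes, 1 gilt lay far from the other 3, measured as the gap to the nearest gilt over the whole range; chance flags about 1 in 20. MBL2 in liver stood at 2.16 in gilt 4 and between 1.34 and 1.45 in the others (ratio 0.859). PDCD1LG2 in muscle was -0.27 in gilt 1 and between -0.16 and -0.14 in the others (ratio 0.889). PROC, liver minus brain stem, was 2.49 in gilt 4 and 2.83 to 2.85 in the others (ratio 0.937), and FOLR1 was 3.15 in gilt 4 and 2.45 to 2.56 in the others (ratio 0.833). PGK2, muscle minus brain stem, was 3.27 in gilt 2 and 4.47 to 4.63 in the others (ratio 0.879), while IFN-DELTA-1 was -0.31 in gilt 4 and -1.62 to -1.57 in the others (ratio 0.962). TSPO, muscle minus uterine endothelium, was -2.98 in gilt 1 and -1.30 to -1.01 in the others (ratio 0.853).

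Rows next to a row with a tissue value of at least 2 shared part of its differences. With strong neighbours left out, the slope was 0.0803 ± 0.00607 (SE) at the next row and 0.0144 ± 0.00506 at the previous one, and with a bound of 1.5, also tried, 0.0638 and 0.0188. Each SE of a slope is over pairs of rows of the same arrays, 345 and 373 pairs at the bound of 2. It does not measure the spread between gilts. Carry-over between spots in printing order may account for the one-sided part. The mean slope over both sides, 0.0460 with pairs of strong rows left out, argues against pairs of strong related probes as the whole cause. Related probes that share only a small part of a difference were not left out, so they stay open. A local scanning artefact also stays open. The larger slope 18 or 24 rows away was 0.00598 ± 0.00351, and the true layout is not stated. No biological explanation was tested.

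Genes of tissues not sampled had a median of 0.06 and a mean of -0.0019 in brain stem, with 4 higher, 4 lower and 14 not past the test, so the list as a whole did not differ by its test. The median was above 0 in 4 of 4 gilts, and 0.0407 without gilt 4, the lowest with 1 gilt left out, which argues against 1 poor sample as its source. The most frequent brain stem difference over all rows was 0.0419, against a median of all rows of -0.01, so the centring of the arrays may account for part of the list's median. Centring on the 336 run-end rows, which lay at 0.14 in brain stem, moved all rows alike and took the list's median to -0.0800, which decides nothing about a background level that differs by tissue. That explanation and a difference between the tissues themselves stay open. The list's median was above 0 in brain stem alone. It was -0.05 in liver and -0.0051 in skeletal muscle, above 0 in 2 and 3 of 4 gilts. Each tissue was set against the mean of the other 3, so these values are not independent of one another. In uterine endothelium the list had a median of -0.10, above 0 in 0 of 4 gilts, with 0 higher and 4 lower (camera adjusted p = 0.17, fry adjusted p = 0.010). In skeletal muscle 5 were higher and 1 lower (camera adjusted p = 0.51, fry adjusted p = 0.042).

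More rows were lowest than highest in brain stem by at least 1 (517 and 372). Without the last 16 rows of each run these counts were 414 and 371, so much of the excess lay in those rows. With any 1 gilt left out rows lowest by at least 1 stayed more numerous. The excess was smallest without gilt 4, at 36 (362 lowest and 326 highest), a value not tested against 0. The counts therefore do not exclude 1 poor sample as the source of much of the excess. A centre pulled down by many low rows would raise brain stem values, so it would not by itself make rows lowest. The most frequent brain stem difference lay above the median by 0.0444 ± 0.0038 (SE), and above it in 4 of 4 gilts. An excess of low rows gives such a gap whatever its source, so the gap is no separate test of the centring. A difference between the tissues, which the design names, was not tested, and the counts trade places if the sign of the ratio is turned.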

How the results depend on the processing

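All 11 total counts (the F test, 6 pairwise comparisons and rows highest in 4 tissues) stayed within 1.5 times the values reported under median centring, scaling, robust moderation, the filter on rows of small SD and both other fits; with no replicate block 14503 rows passed the F test and with a random block 13592, against 12699. The smaller counts of rows lowest moved further: with scaling 160 in liver and 280 in muscle, against 92 and 140, with no replicate block 276 in muscle and 224 in uterine endothelium, against 128, and with a random block 213 in muscle. The filter on missing values removed nothing and so tested nothing. Averaging the probes of a gene touched only ASIP, and no alternative to it was run. Leaving out 1 gilt gave 3103 to 4487 rows for skeletal muscle versus uterine endothelium, 2785 to 3978 for liver versus uterine endothelium, 5611 to 7849 for uterine endothelium versus brain stem, 571 to 1047 highest in uterine endothelium, 1259 to 1613 highest in brain stem, and 4 to 45 with a dye effect; fewer gilts leave fewer degrees of freedom. The run-end centring and the turned signs were chosen after the data were seen. Tissues centred on the run ends gave 977 rows highest in brain stem, where those rows lay at 0.14; the cause was not tested. With all signs turned, 92, 140, 128 and 1688 rows were highest in liver, muscle, uterine endothelium and brain stem, by construction. Of 24 list tests, 2 passed with camera, 0 with an estimated correlation and 15 with fry, which asks another question. Among 87 values of named genes, 66 kept their call under every alternative that tested them, and 0 changed direction. LALBA, GLRB and PDCD1LG2 had their rows removed with those that follow a strong row, so that alternative did not test them. Except for CEND1, GAD2 and GLRB, the genes were chosen for 1 direction in every gilt, so leaving out a gilt could not turn them. Robust moderation and the removal of other rows leave a difference as it is. Turning all signs was not among these alternatives and turns each value by construction. Without intensities, what signal over background limits is unknown.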

Other observations

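FOLR1 stood at 1.15 ± 0.12 (SD, n = 4) in liver and 1.05 ± 0.24 in uterine endothelium, against -0.68 ± 0.39 in muscle and -1.52 ± 0.37 in brain stem. JUN stood at 1.02 ± 0.34 in muscle and 0.88 ± 0.63 in uterine endothelium, and at -1.05 ± 0.45 in liver and -0.85 ± 1.06 in brain stem, where gilt 4 was at -2.44 and the others between -0.33 and -0.30. TYROBP, an adaptor of myeloid and natural killer cells, was 0.50 ± 0.34 in uterine endothelium and -0.50 ± 0.21 in muscle, and CSN1S1, a milk casein, 0.43 ± 0.10 in muscle and -0.46 ± 0.25 in uterine endothelium. UTS2, urotensin 2, was 0.53 ± 0.15 in liver and -0.43 ± 0.28 in uterine endothelium. These genes were chosen after their values were seen, except FOLR1 and JUN. Against the mean of the other 3 tissues, the liver genes as a list had a median of -0.62 in uterine endothelium (camera adjusted p = 0.0099, or 0.45 with an estimated correlation). The median was -0.37 in muscle (camera adjusted p = 0.052) and -0.82 in brain stem (camera adjusted p = 0.26). That mean includes liver, so the rise in liver by itself lowers all of these values, and they are no separate result.

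Tissue names were exchanged within gilts 2, 3 and 4 in 99 random ways, which with the real one make 100. The real labels alone reached their count in each case, 1 of 100, which is the smallest share that 100 labellings can give. Chance assignment of the names is therefore unlikely, not excluded. The labelling that gave 7924 rows by the F test, 1259 highest in muscle and 1789 in brain stem kept 14 of 16 names in place. The real count and the highest other were 12699 and 7924 for the F test, 7796 and 5679 for liver versus brain stem, 5408 and 2940 for liver versus skeletal muscle, 4969 and 1787 for liver versus uterine endothelium, 8103 and 6542 for skeletal muscle versus brain stem, 5475 and 2525 for skeletal muscle versus uterine endothelium, and 8662 and 6284 for uterine endothelium versus brain stem. For rows highest in a tissue they were 1473 and 1077 in liver, 1475 and 1259 in muscle, 1187 and 348 in uterine endothelium, and 2012 and 1789 in brain stem.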
